A study of Homo sapiens with 21 samples.

How the data were processed

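RNA sequencing of poly-A selected RNA was analysed for 21 libraries of the human melanoma cell line SK-MEL-147: 7 groups (untreated cells and 6 compounds) with 3 replicates each. The deposited table holds expected counts from RSEM for 26475 genes, 1 column per library, not scaled between libraries. Per the submitters' processing notes, the authors used Bowtie2 2.1.0 and RSEM 1.2.15 with build hg38; the gene annotation, read filters and other parameters are not given in the sources used here. The raw reads were not used here. Summed expected counts ran from 20978182 to 78776788 per library, and ribosomal RNA genes took 4.99 to 10.6% of them. The chi-square over genes between replicates of a group, divided by its degrees of freedom, was 2.26 to 17.1 over the 21 pairs, and 0 pairs were identical.

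Before the data were examined, the comparisons, tests, gene lists, rule for named genes and a set of alternatives were fixed. Expected counts were rounded to whole numbers, filtered with filterByExpr of edgeR 4.0.16 (minimum count 10, minimum total count 15), and scaled by TMM. All 21 libraries were fitted together with group as the only term, and each compound was tested against untreated cells with the two-sided edgeR quasi-likelihood test. TP-472 was also tested against JQ-1 and GSK-591 against MS023 as direct contrasts. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, over the 15062 genes tested. Fold changes use the edgeR prior count of 0.125. Principal components were computed on log2 CPM.

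The 30 gene lists (pathways, complexes, melanoma states, compound targets and markers of other cell types) held 610 genes, all found in the table (25 under an older symbol), of which 542 were tested. Lists with at least 5 tested genes, 28 in number, were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over all 168 pairs of list and compound, and separately for the direct contrasts. Of the 168, 36 were called, and 8 held with a correlation estimated from the data: NF-kB targets, histones, G1/S, G2/M, anti-apoptotic, oxidative stress and P-TEFb genes with JQ-1, and G1/S genes with TP-472. The rule named, per compound, the 6 called genes with the largest rise and the 6 with the largest fall among those with at least 3 CPM in the higher group and no overlap between groups (4 and 4 in direct contrasts), members of the 8 lists with the smallest camera p, and the compound's targets. For shared changes it named the 6 genes called by the most compounds in 1 direction. For the comparisons it gave 331 pairs of gene and comparison (196 symbols, 323 pairs called). Counts cover all of them, and the text gives part of them as examples; a few of the genes picked are not reported here. Genes named outside the rule are said to be chosen after their values were seen.

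Fixed alternatives were DESeq2 1.42.0 in place of edgeR, RLE scaling, total-count scaling, no filter on low counts, a replicate block, the 2 groups of a comparison fitted alone, the other 5 treated groups as the reference, every library thinned at random to the smallest total, a 1.5-fold threshold (glmTreat), an estimated correlation for lists, and leaving out each replicate in turn. Added after seeing the data were removal of the GC trend of each library (loess of log2 CPM, prior count 2, on transcript GC content, span 0.3, 4 iterations), leaving out ribosomal RNA genes, and taking the other treated groups except JQ-1 as the reference, alone and with the GC trend removed. GC content was taken from GENCODE 29 transcripts and was known for 14572 of the genes tested (96.7%). The 3 fits in the results are that against untreated cells, that with the GC trend removed (fit 2), and fit 2 with the other treated groups except JQ-1 as the reference (fit 3, with the other 5 for JQ-1). Shared changes were set beside 20 simulated sets in which the treated groups did not change. Shares of reads between near-identical genes and GC slopes per library were compared by two-sided exact permutation tests.

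The fit was tested on simulated data with 200 changed genes. With counts as drawn, 36.8 to 48.7% of genes changed 1.2-fold and 82.1 to 85.7% of those changed 2-fold were recovered, and 4 to 13 unchanged genes were called. With a GC trend added to the untreated libraries, 2262 to 2507 unchanged genes were called, and after its removal 5 to 9. The 3 fits and shared changes were also computed on 10 simulated sets with the measured GC trend of each library and no changed gene. Computations used R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.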

Results

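Gene expression was measured by RNA sequencing of poly-A selected RNA in SK-MEL-147, a human melanoma cell line. The 21 libraries formed 7 groups of 3: untreated cells and cells given 1 of 6 compounds that act on chromatin or on arginine. TP-472 binds the bromodomains of BRD9 and BRD7, and JQ-1 binds the BET bromodomain proteins. GSK-591 inhibits the arginine methyltransferase PRMT5, and MS023 inhibits the type I arginine methyltransferases. GSK-484 inhibits the arginine deiminase encoded by PADI4, and UNC0642 inhibits the histone methyltransferases EHMT1 and EHMT2. Doses, times and any vehicle are not given in the sources used here. Summed expected counts ran from 20978182 (GSK-591 replicate 2) to 78776788 (UNC0642 replicate 2), and untreated libraries held 35089548 to 47741066. Of 26475 genes in the table, 15062 had enough counts to be tested, with a common coefficient of variation between replicates of 5.09%. The replicates are called biological but not stated to be separate cultures, so p-values measure only the spread between these samples, which may be technical. Levels are CPM (counts scaled to the TMM-adjusted library total) as mean ± SD with n = 3, and fold changes are log2 values with their SE. Positions are on hg38 with GENCODE 29 gene models.

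JQ-1 stood far from the other groups: the first principal component held 57.4% of the variance, and JQ-1 libraries scored 94.9 to 95.6 on it against -17.3 to -12.8 for the other 18. Against untreated cells, 11037 genes were called with JQ-1 (5377 higher, 5660 lower), 6411 with MS023 (3313 and 3098) and 4952 with GSK-591 (2728 and 2224). Calls numbered 4788 with TP-472 (2602 and 2186), 2872 with GSK-484 (1718 and 1154) and 2448 with UNC0642 (1312 and 1136). Called genes changed by a median of 1.5-fold with JQ-1 and by 1.15-fold to 1.2-fold with the other compounds.

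The untreated libraries differed from all treated ones in a way tied to base composition. The slope of expression on transcript GC content, in log2 CPM per 10 percentage points, averaged -0.13 (SD 0.044, n = 3) in untreated and 0.025 (SD 0.041, n = 18) in treated libraries. A two-sided exact permutation test gave p = 0.000752, the smallest for its 1330 assignments, but treats libraries of a group as independent. Across genes, which are not independent replicates, fold changes followed GC content with Spearman correlations of 0.59 for TP-472, 0.59 for GSK-591, 0.619 for GSK-484, 0.657 for MS023, 0.525 for UNC0642 and 0.18 for JQ-1. Each compound was therefore also fitted with the GC trend of every library removed (fit 2). Fit 3 also put the other treated groups except JQ-1 in place of the untreated cells. Both were added after seeing the data. Genes called in the same direction in all 3 fits numbered 9441 with JQ-1 (4587 higher, 4854 lower), 904 with MS023 (501 and 403), 626 with GSK-591 (365 and 261), 567 with TP-472 (248 and 319), 308 with UNC0642 (173 and 135) and 1 with GSK-484.

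**Figure D1:**
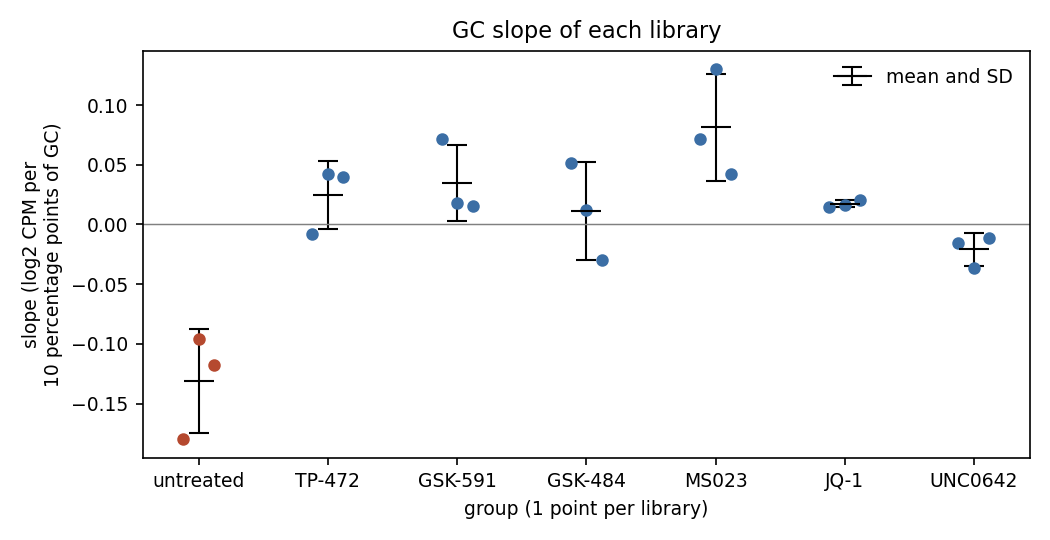
Slope of each library's log2 CPM, relative to each gene's mean without JQ-1, on transcript GC content (per 10 percentage points), with 1 point per library and group mean and SD. The 3 untreated libraries lie between -0.18 and -0.096, and the 18 treated libraries between -0.036 and 0.13.

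**Figure D2:**
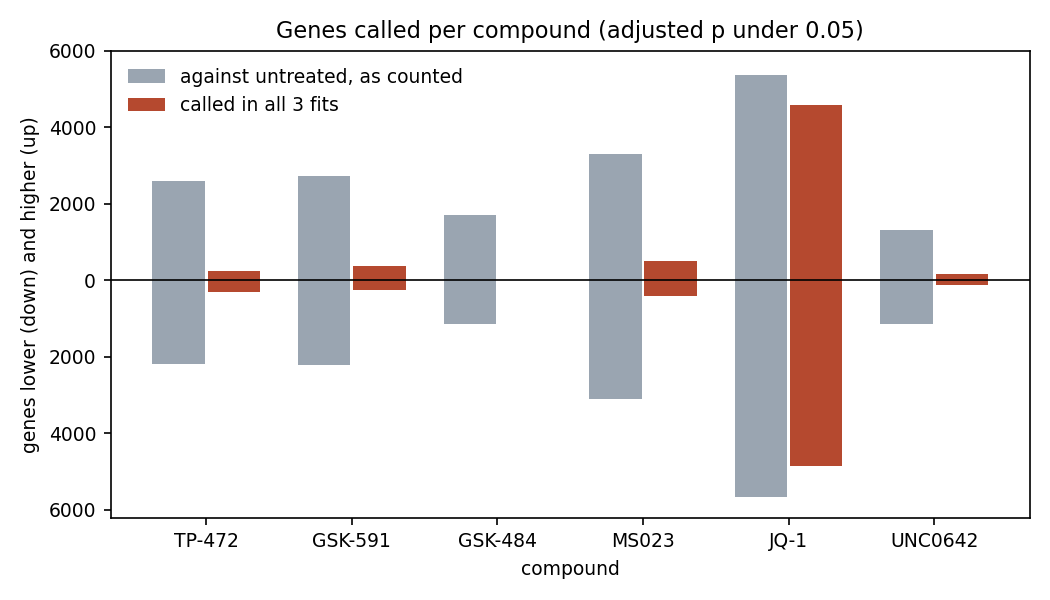
Number of genes higher (up) and lower (down) with each compound at an adjusted p under 0.05, against untreated cells (grey) and in all 3 fits (red). JQ-1 has 9441 genes in all 3 fits and GSK-484 has 1.

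Several of the largest fitted changes shared by the compounds fell on genes that share reads with a near-identical copy or a read-through transcript, and are reported as uncertain. Exact permutation tests of the shares below cannot decide anything, because the genes were picked for their changes between the same libraries. EIF3C held 17.5% of the EIF3C and EIF3CL counts in untreated and 3.2% in treated libraries. NOMO3 held 3.81% of the counts of NOMO1, NOMO2 and NOMO3 in untreated and 0.148% in treated libraries. The read-through TNFAIP8L2-SCNM1 held 3.5% and 50.6% of its counts with SCNM1, and SMN2 held 46.4% and 25.8% of those with SMN1. NOMO3 averaged 13 CPM in untreated cells and had no counts with TP-472 or GSK-591. MINOS1-NBL1 averaged 5.11 CPM and had none with TP-472, GSK-591, GSK-484 or MS023. Genes with fractional expected counts made up 19.5% of genes tested but 26 to 51.1% of those changed at least 2-fold with the 5 compounds other than JQ-1.

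JQ-1 against untreated cells asked what BET bromodomain inhibition changes. Inflammatory genes fell: CXCL8, a neutrophil chemokine (chromosome 4, 73740506 to 73743716), fell from 576 ± 30.6 to 53.6 ± 1.03 CPM (log2 fold change -3.42, SE 0.045, edgeR adjusted p = 1.04e-24), and IL1A, an interleukin, fell from 160 ± 7.12 to 18.2 ± 1.21 CPM (-3.14, SE 0.048). Among inflammatory NF-kB targets, all 20 of the 20 tested fell, also when adjusted over the list alone. NF-kB targets with JQ-1 had a median of -1.95 (camera adjusted p = 7.17e-27, 7.73e-05 with an estimated correlation, and 1.6e-26 and 2.16e-23 in fits 2 and 3). Members included CXCL1 (-3.44, SE 0.063) and IL1B (-1.87, SE 0.040). Poly-A tailed histone transcripts, the only ones selected, rose: 12 of the 12 tested, also adjusted over the list alone. Histone genes with JQ-1 had a median of 2.36 (camera adjusted p = 1.89e-07, 0.0236 with an estimated correlation, and 3.79e-07 and 4.58e-10 in fits 2 and 3). HIST2H2BE (chromosome 1, 149884459 to 149886652) rose from 2.12 ± 0.137 to 32.8 ± 1.29 CPM (log2 fold change 3.95, SE 0.12, edgeR adjusted p = 1.9e-18), and the linker histone gene H1F0 rose by 1.85. Related histone genes share sequence, HIST2H4A and HIST2H4B had identical values, and HIST2H2AA3 and HIST1H2BD (3.78 and 3.39) are likewise uncertain.

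Genes of the cell cycle fell. In the list for G1/S and DNA replication, 1 rose, 22 fell and 1 did not pass of 24 tested, with the same counts adjusted over the list alone. G1/S genes with JQ-1 had a median of -0.56 (camera adjusted p = 2.19e-06, 0.0236 with an estimated correlation, and 6.04e-07 and 3.49e-07 in fits 2 and 3). Falls included RRM2 (-1.14, SE 0.032), GINS1 (-1.33, SE 0.054) and TYMS (-1.02, SE 0.044), while CLSPN, a replication checkpoint adaptor, rose (0.33, SE 0.067). For G2/M and mitosis, 2 rose, 21 fell and 1 did not pass of 24 tested, with the same counts adjusted over the list alone. G2/M genes with JQ-1 had a median of -0.66 (camera adjusted p = 2.19e-06, 0.0309 with an estimated correlation, and 4.57e-05 and 3.07e-06 in fits 2 and 3). The mitotic genes AURKA (-0.88, SE 0.035), CCNA2 (-0.98, SE 0.040) and UBE2C (-1.06, SE 0.044) fell and CDC20 rose (0.46, SE 0.043). Of genes that restrain apoptosis, 8 fell and 2 did not pass of 10 tested, with the same counts adjusted over the list alone. Anti-apoptotic genes with JQ-1 had a median of -0.86 (camera adjusted p = 7.29e-06, 0.0126 with an estimated correlation, and 1.05e-05 and 7.7e-05 in fits 2 and 3). CFLAR, an inhibitor of caspase activation, fell from 46.4 ± 1.58 to 11.3 ± 0.202 CPM (log2 fold change -2.04, SE 0.052, edgeR adjusted p = 1.08e-19). Further falls were in BIRC3 (-2.03, SE 0.061), MCL1 (-0.83, SE 0.032) and BIRC2 (-0.87, SE 0.044).

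Genes of the oxidative stress response and metallothioneins rose: 14 rose, 1 fell and 1 did not pass of 16 tested, with the same counts adjusted over the list alone. Oxidative stress genes with JQ-1 had a median of 0.69 (camera adjusted p = 0.000124, 0.0423 with an estimated correlation, and 0.000143 and 9.03e-06 in fits 2 and 3). TXNRD1, a thioredoxin reductase, rose from 400 ± 12 to 1240 ± 5.67 CPM (log2 fold change 1.63, SE 0.034, edgeR adjusted p = 2.81e-21), MT1X by 2.63 (SE 0.12) and PGD by 0.75, while ME1 fell (-0.86, SE 0.052). In the list of P-TEFb subunits and genes known to respond to BET inhibitors, 10 rose, 4 fell and 2 did not pass of 16 tested, with the same counts adjusted over the list alone. P-TEFb response genes with JQ-1 had a median of 0.22 (camera adjusted p = 0.000781, 0.0236 with an estimated correlation, and 0.00293 and 9.93e-05 in fits 2 and 3). HEXIM1, an inhibitor of P-TEFb, rose from 63.3 ± 2.64 to 209 ± 7.58 CPM (log2 fold change 1.73, SE 0.045, edgeR adjusted p = 1.59e-19), as did POLR2A, the largest subunit of RNA polymerase II (1.81, SE 0.068). MYC, a growth-promoting transcription factor (chromosome 8, 127735434 to 127741434), was higher with JQ-1 at 124 ± 1.34 CPM against 39.1 ± 1.81 (log2 fold change 1.66, SE 0.051, edgeR adjusted p = 3.17e-18). FOSL1 (-0.36, SE 0.039) and the cyclin gene CCNT2 (-0.45, SE 0.059) fell. Among the targets of JQ-1, BRD2 (chromosome 6, 32968660 to 32981505) rose from 236 ± 4.18 to 629 ± 8.97 CPM (log2 fold change 1.41, SE 0.034, edgeR adjusted p = 3.64e-20). BRD3 rose by 0.19 (edgeR adjusted p = 0.00272), and this call ended in fit 2 (edgeR adjusted p = 0.899). BRDT, with a highest count of 1, was not tested.

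**Figure D3:**
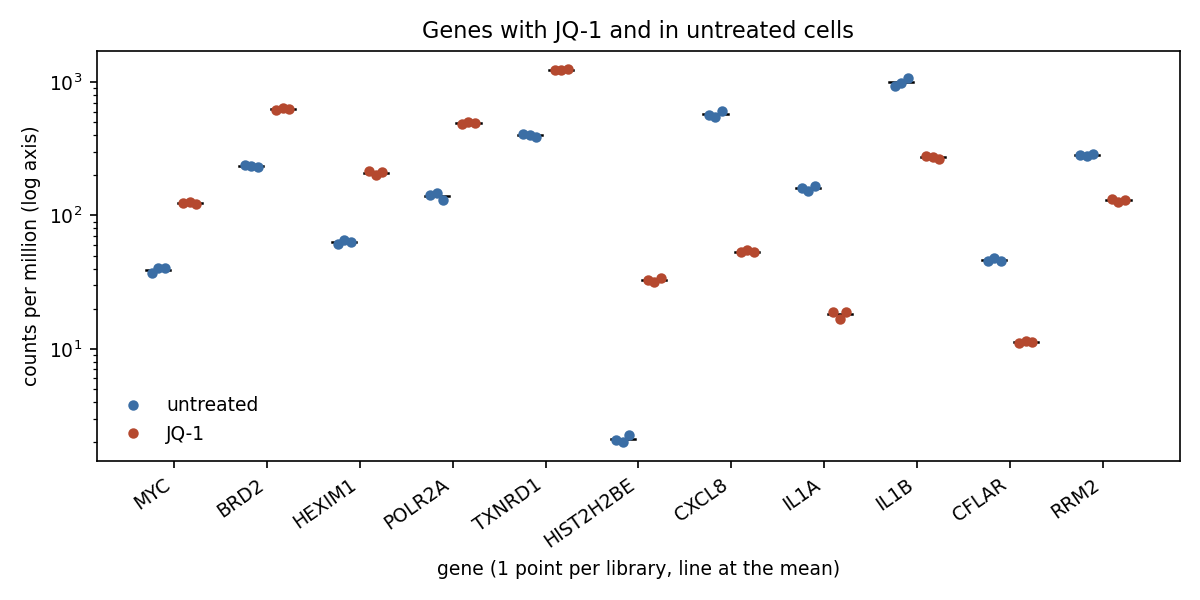
CPM, counts scaled to the library total (log axis), of the genes named in the 3 untreated and the 3 JQ-1 libraries, with a line at each mean. MYC, BRD2, HEXIM1, POLR2A, TXNRD1 and HIST2H2BE are higher with JQ-1, and CXCL8, IL1A, IL1B, CFLAR and RRM2 are lower.

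Calls for 3 further lists with JQ-1 were lost with an estimated correlation. For antigen presentation, 2 rose, 11 fell and 3 did not pass of 16 tested, with the same counts adjusted over the list alone. Antigen presentation genes with JQ-1 had a median of -0.48 (camera adjusted p = 0.00269, 0.195 with an estimated correlation, and 0.000243 and 7.66e-05 in fits 2 and 3). The peptide-trimming gene ERAP2 fell from 49.1 ± 1.29 to 9.91 ± 0.905 CPM (-2.31, SE 0.058) and the immunoproteasome gene PSMB8 fell by 1.51 on the log2 scale. CALR, a peptide-loading chaperone, rose (0.12, SE 0.036) but was called in neither fit 2 nor fit 3, and its sign turned with total-count scaling (-0.025). Among interferon-stimulated genes, 5 rose, 17 fell and 3 did not pass of 25 tested, with the same counts adjusted over the list alone. Interferon-stimulated genes with JQ-1 had a median of -1.14 (camera adjusted p = 0.0299, 0.109 with an estimated correlation, and 0.0539 and 0.0394 in fits 2 and 3). In the lysosome list, 17 rose, 1 fell and 4 did not pass of 22 tested, with the same counts adjusted over the list alone. Lysosome genes with JQ-1 had a median of 0.27 (camera adjusted p = 0.01, 0.365 with an estimated correlation, and 0.0183 and 0.0304 in fits 2 and 3). The largest fitted falls were in CSF3, a cytokine gene (chromosome 17, 40015361 to 40017813), EHF, CSF2, CCR1, DMBT1 and MYPN. CSF3 had 721 counts in the untreated and 2 in the JQ-1 libraries, a ratio of 292 (95% interval 80.4 to 2410). EHF, an epithelial transcription factor, had 3988 and 15 (ratio 215, 130 to 385). These intervals cover counting error only. The largest rises outside the histone genes were in KIAA1683 (log2 fold change 5.11, SE 0.27, edgeR adjusted p = 4.82e-14) and EFR3B (log2 fold change 4.09, SE 0.14, edgeR adjusted p = 2.03e-17). Scaled by total counts, 37.3% of the called genes were higher with JQ-1 against 48.7% above. That scaling moved the median of all genes from -0.0064 to -0.15 (log2), and changes are given relative to the median gene.

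TP-472 against untreated cells asked what inhibition of BRD9 and BRD7 changes. Of integrated stress response genes, 13 rose and 9 did not pass of 22 tested, and 15 rose and 1 fell adjusted over the list alone. Stress response genes with TP-472 had a median of 0.20 (camera adjusted p = 1.37e-08, 0.0846 with an estimated correlation, and 6.84e-08 and 2.02e-15 in fits 2 and 3). In fit 2, 14 were higher and 2 lower (17 and 2 adjusted over the list alone), and 11 were higher in all 3 fits. CHAC1, a glutathione-degrading enzyme (chromosome 15, 40952962 to 40956519), rose from 19 ± 0.721 to 27.5 ± 0.862 CPM (log2 fold change 0.54, SE 0.058, edgeR adjusted p = 3.88e-06), and the serine-pathway genes PHGDH (0.36, SE 0.047) and SHMT2 (0.23, SE 0.032) rose, as did SESN2 (0.33, SE 0.042). Of genes for G1/S and DNA replication, 13 rose and 11 did not pass of 24 tested, and 14 rose adjusted over the list alone. G1/S genes with TP-472 had a median of 0.12 (camera adjusted p = 7.29e-06, 0.0309 with an estimated correlation, and 5.31e-11 and 4.25e-26 in fits 2 and 3). In fit 2, 15 were higher (19 adjusted over the list alone), and 10 were higher in all 3 fits. The replication helicase gene MCM2 (chromosome 3, 127598223 to 127622436) rose from 122 ± 3.47 to 152 ± 2.52 CPM (log2 fold change 0.31, SE 0.038, edgeR adjusted p = 1.74e-05), with E2F1 (0.35, SE 0.043), MCM5 (0.36, SE 0.049) and CDT1 (0.50, SE 0.068).

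The theme of the matrix list and of the apoptosis lists was chosen in knowledge of the published study's theme, so their counts are not independent evidence. For genes of the extracellular matrix and its receptors with TP-472, 8 rose, 13 fell and 18 did not pass of 39 tested, and 9 rose and 14 fell adjusted over the list alone. Matrix genes with TP-472 had a median of -0.076 (camera adjusted p = 0.0383, 0.767 with an estimated correlation, and 3.21e-08 and 2.3e-15 in fits 2 and 3). In fit 2, 1 was higher and 10 lower (2 and 15 adjusted over the list alone), and 8 were lower in all 3 fits. The collagen cross-linking enzyme LOX fell from 119 ± 4.66 to 93.1 ± 3.54 CPM (log2 fold change -0.36, SE 0.043, edgeR adjusted p = 1.45e-05). The integrin genes ITGB8 (-0.50, SE 0.061), ITGAV (-0.42, SE 0.065) and ITGB1 (-0.21, SE 0.030) fell, and ITGB5 (0.20, SE 0.037) and COL6A2 (0.26, SE 0.050) rose. The 8 lower in all 3 fits were ITGA10, ITGAV, ITGB1, ITGB3, ITGB8, LOX, SDC1 and THBS1. Among anti-apoptotic genes, 5 fell and 5 did not pass of 10 tested, with the same counts adjusted over the list alone. Anti-apoptotic genes with TP-472 had a median of -0.13 (camera adjusted p = 0.0234, 0.135 with an estimated correlation, and 0.0207 and 0.531 in fits 2 and 3). In fit 2, 4 were lower (the same adjusted over the list alone), and 1 was lower in all 3 fits. The falls included XIAP (-0.29, SE 0.045), BIRC2 (-0.28, SE 0.043), MCL1 (-0.21, SE 0.032) and BCL2L2 (-0.12, SE 0.043). For spliceosomal Sm proteins and PRMT enzymes, 9 rose, 1 fell and 10 did not pass of 20 tested, with the same counts adjusted over the list alone. Sm and PRMT genes with TP-472 had a median of 0.11 (camera adjusted p = 0.041, 0.702 with an estimated correlation, and 0.0118 and 0.008 in fits 2 and 3). In fit 2, 6 were higher (9 adjusted over the list alone), and 2 were higher in all 3 fits. Rises included PRMT1 (0.31, SE 0.051), SNRPB (0.29, SE 0.054), LSM4 (0.31, SE 0.062) and PRMT5 (0.13, SE 0.030), and PRMT3 fell (-0.19, SE 0.052). COL6A2 and PRMT3 were called in neither fit 2 nor fit 3, and ITGB5, XIAP, MCL1, BCL2L2, PRMT1, SNRPB and PRMT5 were not called in fit 3.

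With TP-472, of the genes encoding the 6 compounds' targets, 7 rose, 1 fell and 5 did not pass of 13 tested, with the same counts adjusted over the list alone. Target genes with TP-472 had a median of 0.12 (camera adjusted p = 0.0458, 0.391 with an estimated correlation, and 0.283 and 0.728 in fits 2 and 3). In fit 2, 4 were higher (5 higher and 1 lower adjusted over the list alone). BRD9 (chromosome 5, 850291 to 892824) rose from 124 ± 1.92 to 135 ± 1.07 CPM (log2 fold change 0.12, SE 0.030, edgeR adjusted p = 0.00454). BRD7 did not pass (0.050, SE 0.037, edgeR adjusted p = 0.327) but was called in fit 2 (0.12, SE 0.032, edgeR adjusted p = 0.0165), and EHMT2 rose by 0.19 (SE 0.050). Named members of 2 lists that were not called moved too: the lysosomal genes CTSD (0.26, SE 0.040) and LAMP2 (-0.22, SE 0.043), and the ribosome biogenesis genes PES1 (0.26, SE 0.041), BOP1 (0.35, SE 0.061) and UTP20 (-0.30, SE 0.068). The largest rises in genes without a near copy were in PLAU, a secreted protease, from 3.15 ± 0.206 to 5.71 ± 0.151 CPM (log2 fold change 0.86, SE 0.10, edgeR adjusted p = 1.29e-05), RTN4R (0.75, SE 0.13) and CTXN1 (0.68, SE 0.13). Without untreated replicate 1, 2789 genes were called. BRD9, EHMT2, CTSD, LAMP2 and BOP1 were called in neither fit 2 nor fit 3, and PES1 was not called in fit 3. UTP20 was not called in fit 2.

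**Figure D4:**
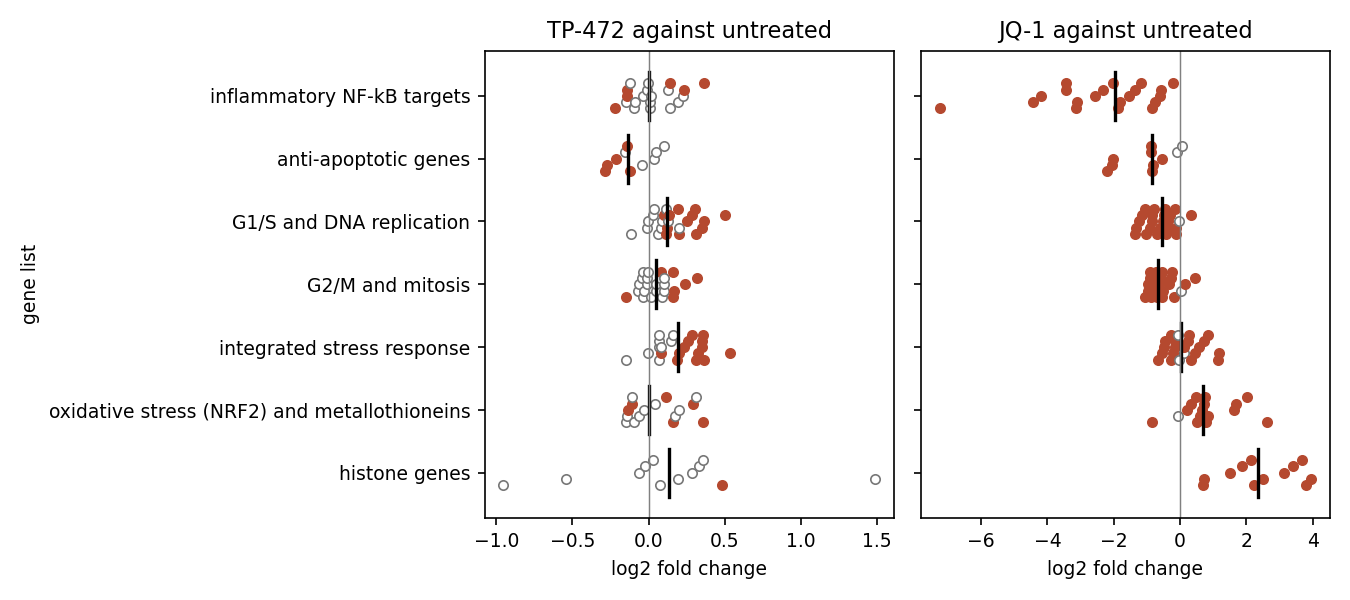
Log2 fold change of each tested member of the gene lists shown, with TP-472 (left) and JQ-1 (right) against untreated cells, on separate scales. Filled points passed an adjusted p of 0.05 and bars mark list medians, which are 0.12 with TP-472 and -0.56 with JQ-1 for G1/S and DNA replication.

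TP-472 and JQ-1 both bind bromodomains, and their direct contrast leaves out the untreated group. It called 10889 genes, 5645 higher and 5244 lower with TP-472 (63.8% higher when scaled by total counts, against 51.8%). Genes for G1/S and DNA replication were higher with TP-472: 23 were higher and 1 did not pass of 24 tested, with the same counts adjusted over the list alone. G1/S genes in this contrast had a median of 0.80 (camera adjusted p = 8.98e-11, 0.00206 with an estimated correlation). NF-kB targets were higher too, with 20 of 20 also adjusted over the list alone. NF-kB targets in this contrast had a median of 1.89 (camera adjusted p = 8.25e-30, 1.7e-05 with an estimated correlation). Of genes for G2/M and mitosis, 20 were higher, 1 was lower and 3 did not pass of 24 tested, with the same counts adjusted over the list alone. G2/M genes in this contrast had a median of 0.71 (camera adjusted p = 2.5e-08, 0.00491 with an estimated correlation). Of anti-apoptotic genes, 8 were higher and 2 did not pass of 10 tested, with the same counts adjusted over the list alone. Anti-apoptotic genes in this contrast had a median of 0.63 (camera adjusted p = 6.06e-05, 0.00491 with an estimated correlation). All 12 histone genes tested were lower with TP-472, also adjusted over the list alone. Histone genes in this contrast had a median of -2.60 (camera adjusted p = 7.27e-08, 0.00491 with an estimated correlation). Of oxidative stress genes, 1 was higher, 13 were lower and 2 did not pass of 16 tested, with the same counts adjusted over the list alone. Oxidative stress genes in this contrast had a median of -0.64 (camera adjusted p = 5.17e-05, 0.0129 with an estimated correlation). Of P-TEFb and BET-inhibitor response genes, 3 were higher, 9 were lower and 4 did not pass of 16 tested, with the same counts adjusted over the list alone. P-TEFb response genes in this contrast had a median of -0.24 (camera adjusted p = 0.000186, 0.00491 with an estimated correlation). Interferon-stimulated genes were mostly higher: 18 were higher, 4 were lower and 3 did not pass of 25 tested, with the same counts adjusted over the list alone. Interferon-stimulated genes in this contrast had a median of 1.06 (camera adjusted p = 0.0165, 0.0384 with an estimated correlation). The calls for antigen presentation, lysosome and hypoxia were lost with an estimated correlation. For antigen presentation, 12 were higher, 1 was lower and 3 did not pass of 16 tested, with the same counts adjusted over the list alone. Antigen presentation genes in this contrast had a median of 0.58 (camera adjusted p = 9.44e-05, 0.0571 with an estimated correlation). For the lysosome, 2 were higher, 16 were lower and 4 did not pass of 22 tested, with the same counts adjusted over the list alone. Their median was -0.21 (camera adjusted p = 0.0228, 0.348 with an estimated correlation). For hypoxia, 3 were higher, 13 were lower and 4 did not pass of 20 tested, with the same counts adjusted over the list alone. Their median was -0.45 (camera adjusted p = 0.0274, 0.178 with an estimated correlation). The largest differences by the rule were in CSF3, CSF2, EHF and DMBT1, higher with TP-472 (7.44 for CSF2). They were also in KIAA1683, HIST2H4A, HIST2H4B and HIST2H2BE, lower (-4.35, SE 0.25 for KIAA1683).

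MS023 against untreated cells asked what inhibition of type I arginine methyltransferases changes. Of antigen presentation genes, 11 rose and 5 did not pass of 16 tested, with the same counts adjusted over the list alone. Antigen presentation genes with MS023 had a median of 0.25 (camera adjusted p = 0.000124, 0.109 with an estimated correlation, and 0.00293 and 0.000143 in fits 2 and 3). In fit 2, 8 were higher and 1 lower (10 and 1 adjusted over the list alone), and 4 were higher in all 3 fits. HLA-C, a class I antigen-presenting molecule (chromosome 6, 31268749 to 31272130), rose from 633 ± 35.7 to 857 ± 31.9 CPM (log2 fold change 0.44, SE 0.041, edgeR adjusted p = 1.33e-07). HLA genes share sequence and are uncertain, and HLA-E, which rose (0.30, SE 0.033), turned sign with the GC trend removed (-0.012). Members higher in all 3 fits included CALR, HLA-B and HLA-C. For hypoxia and glycolysis, 9 rose and 11 did not pass of 20 tested, with the same counts adjusted over the list alone. Hypoxia genes with MS023 had a median of 0.10 (camera adjusted p = 0.0217, 0.245 with an estimated correlation, and 0.0107 and 1.61e-05 in fits 2 and 3). In fit 2, 10 were higher and 1 lower (11 and 1 adjusted over the list alone), and 4 were higher in all 3 fits. NDRG1 (chromosome 8, 133237171 to 133302022) rose from 203 ± 4.98 to 258 ± 1.57 CPM (log2 fold change 0.35, SE 0.033, edgeR adjusted p = 1.69e-07), with ENO2 (0.32, SE 0.034), SLC2A1 (0.25, SE 0.038) and VEGFA (0.18, SE 0.033). VEGFA was called in neither fit 2 nor fit 3, and HLA-E was not called in fit 2.

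In the lysosome list with MS023, 13 rose, 2 fell and 7 did not pass of 22 tested, and 14 rose and 2 fell adjusted over the list alone. Lysosome genes with MS023 had a median of 0.18 (camera adjusted p = 0.000781, 0.245 with an estimated correlation, and 0.00983 and 0.0156 in fits 2 and 3). In fit 2, 7 were higher (10 adjusted over the list alone), and 2 were higher in all 3 fits. Here CTSD (0.40, SE 0.040) and SQSTM1 (0.42, SE 0.043) rose and LAMP2 fell (-0.21, SE 0.043). Of anti-apoptotic genes, 6 fell and 4 did not pass of 10 tested, with the same counts adjusted over the list alone. Anti-apoptotic genes with MS023 had a median of -0.18 (camera adjusted p = 0.015, 0.11 with an estimated correlation, and 0.00873 and 0.1 in fits 2 and 3). In fit 2, 1 was higher and 3 lower (2 and 6 adjusted over the list alone), and 2 were lower in all 3 fits. BCL2, an inhibitor of mitochondrial apoptosis, fell from 16.9 ± 1.28 to 10.9 ± 0.928 CPM (log2 fold change -0.65, SE 0.076, edgeR adjusted p = 1.45e-06). Smaller falls were in MCL1 (-0.20, SE 0.032), BIRC2 (-0.26, SE 0.043) and XIAP (-0.25, SE 0.045). In the integrated stress response list, 13 rose, 4 fell and 5 did not pass of 22 tested, with the same counts adjusted over the list alone. Stress response genes with MS023 had a median of 0.16 (camera adjusted p = 0.0234, 0.549 with an estimated correlation, and 0.592 and 0.78 in fits 2 and 3). In fit 2, 7 were higher and 2 lower (the same adjusted over the list alone), and 2 were higher and 1 lower in all 3 fits. The genes PHGDH (0.35, SE 0.047) and CHAC1 (0.42, SE 0.058) rose and SLC7A11 (-0.34, SE 0.060) and MTHFD2 (-0.14, SE 0.029) fell. Lists that were not called held named members that moved: the neural crest genes NGFR (0.49, SE 0.041) and L1CAM (0.35, SE 0.042), the matrix genes COL6A2 (0.51, SE 0.050), ITGA3 (0.34, SE 0.035) and ITGAV (-0.45, SE 0.065), and the SWI/SNF genes SMARCB1 (0.28, SE 0.039), SMARCA4 (0.28, SE 0.042) and PBRM1 (-0.33, SE 0.056). Among its targets, PRMT1 rose from 178 ± 15.9 to 236 ± 9.84 CPM (log2 fold change 0.41, SE 0.051, edgeR adjusted p = 2.26e-06) and PRMT3 fell from 32.5 ± 1.97 to 24.8 ± 1.02 CPM (log2 fold change -0.39, SE 0.053, edgeR adjusted p = 5.58e-06). CARM1 rose (0.22, SE 0.048) but turned sign with the GC trend removed (-0.013), PRMT6 fell (-0.17, SE 0.059), and PRMT8, with a highest count of 1, was not tested. OPN3, an opsin (chromosome 1, 241590102 to 241677376), fell from 20.4 ± 1.69 to 7.97 ± 0.519 CPM (log2 fold change -1.36, SE 0.079, edgeR adjusted p = 7.83e-11), and ADM5 (1.29, SE 0.16) and CDK3 (1.06, SE 0.17) rose, CDK3 being 0.35 in fit 3 (edgeR adjusted p = 0.0524). Scaled by total counts, 38.9% of called genes were higher against 51.7%, and with the GC trend removed 63.2% were. LAMP2, MCL1, BIRC2, SLC7A11, MTHFD2, SMARCA4 and CARM1 were called in neither fit 2 nor fit 3, and CTSD, XIAP, CHAC1, L1CAM, ITGAV, SMARCB1 and PBRM1 were not called in fit 3. PRMT6 was not called in fit 2.

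GSK-591 against untreated cells asked what inhibition of PRMT5 changes. Of lysosomal genes, 11 rose, 1 fell and 10 did not pass of 22 tested, and 12 rose and 2 fell adjusted over the list alone. Lysosome genes with GSK-591 had a median of 0.15 (camera adjusted p = 0.000885, 0.245 with an estimated correlation, and 0.0138 and 0.0553 in fits 2 and 3). In fit 2, 7 were higher (the same adjusted over the list alone), and 3 were higher in all 3 fits. The protease gene CTSD (chromosome 11, 1752752 to 1764573) rose from 237 ± 9.13 to 303 ± 13.5 CPM (log2 fold change 0.36, SE 0.040, edgeR adjusted p = 4.82e-06), with CTSB (0.22, SE 0.033) and SQSTM1 (0.26, SE 0.044), while LAMP2 fell (-0.13, SE 0.043) and turned sign with the GC trend removed (0.039). Of targets of the tumour suppressor p53, 10 rose, 2 fell and 12 did not pass of 24 tested, and 11 rose and 3 fell adjusted over the list alone. Targets of p53 with GSK-591 had a median of 0.10 (camera adjusted p = 0.0249, 0.106 with an estimated correlation, and 0.0361 and 4.93e-08 in fits 2 and 3). In fit 2, 7 were higher (the same adjusted over the list alone), and 3 were higher in all 3 fits. The pro-apoptotic gene BBC3 rose from 24.9 ± 0.816 to 33.7 ± 1.58 CPM (log2 fold change 0.43, SE 0.051, edgeR adjusted p = 7.12e-06), with PHLDA3 (0.47, SE 0.066) and CDKN1A (0.22, SE 0.040), and TP53INP1 (-0.21, SE 0.058) and MDM2 (-0.12, SE 0.045) fell. SQSTM1, LAMP2 and TP53INP1 were called in neither fit 2 nor fit 3, and CDKN1A was not called in fit 2. MDM2 was not called in fit 2 and was higher in fit 3 (0.15, edgeR adjusted p = 0.00114).

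In the dedifferentiated invasive melanoma list with GSK-591, 9 rose, 3 fell and 11 did not pass of 23 tested, and 10 rose and 4 fell adjusted over the list alone. Invasive-state genes with GSK-591 had a median of 0.079 (camera adjusted p = 0.0299, 0.365 with an estimated correlation, and 0.624 and 9.93e-05 in fits 2 and 3). In fit 2, 4 were higher and 2 lower (6 and 6 adjusted over the list alone), and 4 were higher in all 3 fits. TGFBI, a matrix protein gene, rose from 2127 ± 79.9 to 2579 ± 17 CPM (log2 fold change 0.28, SE 0.029, edgeR adjusted p = 2.07e-06), with TGFB1 (0.49, SE 0.072), FOSL1 (0.27, SE 0.039) and LOXL2 (0.22, SE 0.031), and NT5E (-0.15, SE 0.031) and ZEB1 (-0.26, SE 0.057) fell. For antigen presentation, 9 rose, 1 fell and 6 did not pass of 16 tested, with the same counts adjusted over the list alone. Antigen presentation genes with GSK-591 had a median of 0.12 (camera adjusted p = 0.0249, 0.355 with an estimated correlation, and 0.506 and 0.894 in fits 2 and 3). In fit 2, 4 were higher (4 higher and 1 lower adjusted over the list alone). TAP1 rose (0.23, SE 0.041) and ERAP1 fell (-0.21, SE 0.053). PRMT5 itself rose from 79.5 ± 1.25 to 85.6 ± 0.889 CPM (log2 fold change 0.11, SE 0.031, edgeR adjusted p = 0.0101). Named members of lists that were not called were NGFR (0.27, SE 0.042), L1CAM (0.27, SE 0.042), BAX (0.22, SE 0.051) and PMAIP1 (-0.22, SE 0.040). IDUA, a lysosomal hydrolase gene, rose from 1.88 ± 0.108 to 3.63 ± 0.267 CPM (log2 fold change 0.95, SE 0.14, edgeR adjusted p = 3.87e-05), but was 0.17 in fit 3 (edgeR adjusted p = 0.252). Scaled by total counts, 32.1% of called genes were higher against 55.1%, and with the GC trend removed 66.5% were. Without untreated replicate 1, 3213 genes were called. FOSL1, LOXL2, ZEB1, NGFR and L1CAM were called in neither fit 2 nor fit 3, and TAP1, PRMT5 and PMAIP1 were not called in fit 3. ERAP1 and BAX were not called in fit 2. NT5E was not called in fit 2 and was higher in fit 3 (0.16, edgeR adjusted p = 7.74e-05).

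GSK-591 and MS023 both inhibit arginine methyltransferases, and their direct contrast called 1490 genes, 818 higher and 672 lower with GSK-591 (43.7% higher when scaled by total counts, against 54.9%). Of p53 targets, 8 were higher and 16 did not pass of 24 tested, and 12 were higher and 2 were lower adjusted over the list alone. Their median was 0.094 (camera adjusted p = 7.06e-05, 0.00439 with an estimated correlation). Named after their values were seen, MDM2, ZMAT3, SESN1 and CCNG1 were higher by 0.27, 0.32, 0.32 and 0.19. Of integrated stress response genes, 8 were lower and 14 did not pass of 22 tested, and 9 were lower adjusted over the list alone. Their median was -0.072 (camera adjusted p = 3.54e-05, 0.113 with an estimated correlation). Of antigen presentation genes, 3 were lower and 13 did not pass of 16 tested, and 5 were lower adjusted over the list alone. Their median was -0.10 (camera adjusted p = 0.00128, 0.0998 with an estimated correlation). Of hypoxia and glycolysis genes, 2 were lower and 18 did not pass of 20 tested, with the same counts adjusted over the list alone. Their median was -0.068 (camera adjusted p = 0.00359, 0.0773 with an estimated correlation). Of anti-apoptotic genes, 3 were higher, 1 was lower and 6 did not pass of 10 tested, and 5 were higher and 1 was lower adjusted over the list alone. Their median was 0.12 (camera adjusted p = 0.0199, 0.0771 with an estimated correlation). Of invasive melanoma genes, 4 were higher, 3 were lower and 16 did not pass of 23 tested, with the same counts adjusted over the list alone. Their median was 0.0061 (camera adjusted p = 0.0199, 0.235 with an estimated correlation). The largest differences by the rule included OPN3, at 22 ± 0.879 CPM with GSK-591 against 7.97 ± 0.519 (log2 fold change 1.47, SE 0.080, edgeR adjusted p = 3.22e-11), NT5E, an ectonucleotidase (chromosome 6, 85449584 to 85495791; log2 fold change 1.05, SE 0.032, edgeR adjusted p = 2.91e-16), and ADM5 (-0.87, SE 0.16). PHOSPHO2-KLHL23, a read-through, averaged 5.40 CPM with GSK-591 and had no counts with MS023, and RN7SL2, which has near copies, differed by -0.85. Leaving out single libraries left 808 to 1181 genes called.

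UNC0642 against untreated cells asked what inhibition of EHMT1 and EHMT2 changes. Of matrix genes and matrix receptors, 14 rose, 2 fell and 23 did not pass of 39 tested, and 16 rose and 2 fell adjusted over the list alone. Matrix genes with UNC0642 had a median of 0.12 (camera adjusted p = 0.000732, 0.571 with an estimated correlation, and 0.00456 and 1.54e-05 in fits 2 and 3). In fit 2, 3 were higher and 1 lower (14 and 3 adjusted over the list alone), and 2 were higher in all 3 fits. The integrin gene ITGA3 rose from 962 ± 29.4 to 1116 ± 37.7 CPM (log2 fold change 0.21, SE 0.035, edgeR adjusted p = 0.000835), with LAMB2 (0.26, SE 0.045) and COL5A1 (0.30, SE 0.056), and ITGB1 fell (-0.11, SE 0.030). Of inflammatory NF-kB targets, 6 fell and 14 did not pass of 20 tested, and 7 fell adjusted over the list alone. NF-kB targets with UNC0642 had a median of -0.10 (camera adjusted p = 0.00666, 0.135 with an estimated correlation, and 6.16e-06 and 1.61e-05 in fits 2 and 3). In fit 2, 5 were lower (the same adjusted over the list alone), and 3 were lower in all 3 fits. CXCL1, a chemokine gene, fell from 134 ± 8.34 to 99.8 ± 2.23 CPM (log2 fold change -0.42, SE 0.051, edgeR adjusted p = 7.62e-05), and CXCL8 and CSF2 fell by 0.30 and 0.39 on the log2 scale. All 3 held in all 3 fits. For G1/S and DNA replication, 1 rose, 4 fell and 19 did not pass of 24 tested, and 2 rose and 8 fell adjusted over the list alone. G1/S genes with UNC0642 had a median of -0.085 (camera adjusted p = 0.0135, 0.22 with an estimated correlation, and 0.000181 and 9.02e-06 in fits 2 and 3). In fit 2, 4 were lower (7 adjusted over the list alone), and 2 were lower in all 3 fits. Here RRM2 (-0.18, SE 0.031) and GINS1 (-0.23, SE 0.050) fell and MCM2 rose (0.14, SE 0.038). ITGB1 and MCM2 were called in neither fit 2 nor fit 3, and COL5A1 was not called in fit 2.

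Of genes for G2/M and mitosis with UNC0642, 3 rose, 6 fell and 15 did not pass of 24 tested, and 3 rose and 7 fell adjusted over the list alone. G2/M genes with UNC0642 had a median of -0.070 (camera adjusted p = 0.0299, 0.351 with an estimated correlation, and 0.961 and 0.00805 in fits 2 and 3). In fit 2, 1 was higher and 1 lower (the same adjusted over the list alone), and 1 was higher and 1 lower in all 3 fits. Here UBE2C (-0.30, SE 0.042) and CDK1 (-0.22, SE 0.050) fell and the proliferation marker MKI67 rose (0.27, SE 0.089), and the list turned sign in fit 2 (median 0.021). Of neural crest and nerve markers, 3 rose and 6 did not pass of 9 tested, and 4 rose adjusted over the list alone. Neural crest genes with UNC0642 had a median of 0.15 (camera adjusted p = 0.0322, 0.135 with an estimated correlation, and 0.283 and 0.107 in fits 2 and 3). In fit 2, 1 was higher (2 adjusted over the list alone), and 1 was higher in all 3 fits. The rises were in L1CAM (0.26, SE 0.042), NES (0.24, SE 0.043) and NGFR (0.14, SE 0.041). NGFR turned sign in fit 2 (-0.013). Of genes encoding compound targets, 5 rose, 1 fell and 7 did not pass of 13 tested, and 6 rose and 1 fell adjusted over the list alone. Target genes with UNC0642 had a median of 0.092 (camera adjusted p = 0.0322, 0.365 with an estimated correlation, and 0.244 and 0.839 in fits 2 and 3). EHMT1 rose from 67.3 ± 3.75 to 77.5 ± 4.87 CPM (log2 fold change 0.21, SE 0.049, edgeR adjusted p = 0.00725) and EHMT2 rose from 76.3 ± 1.23 to 86 ± 3.06 CPM (log2 fold change 0.18, SE 0.050, edgeR adjusted p = 0.0202). Further named genes were XIAP (-0.19, SE 0.044), WNT5A (-0.30, SE 0.041) and TEAD4 (0.28, SE 0.051). The largest rises outside read-throughs and near copies were in SBSN, an epidermal secreted protein gene (chromosome 19, 35523367 to 35528351), from 4.31 ± 0.713 to 9.04 ± 0.625 CPM (log2 fold change 1.07, SE 0.10, edgeR adjusted p = 2.62e-06), and IGFN1 (log2 fold change 0.91, SE 0.093, edgeR adjusted p = 5.92e-06). Scaled by total counts, 29.7% of called genes were higher against 53.6%. Leaving out untreated replicate 3, UNC0642 replicate 2 or UNC0642 replicate 3 left 1456, 1300 and 1109 genes called. NGFR, EHMT1, EHMT2, XIAP and TEAD4 were called in neither fit 2 nor fit 3, and CDK1 and NES were not called in fit 2.

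GSK-484 against untreated cells asked what inhibition of the deiminase PADI4 changes. PADI4 had a highest count of 11 and was not tested. Of antigen presentation genes, 8 rose and 8 did not pass of 16 tested, and 9 rose adjusted over the list alone. Antigen presentation genes with GSK-484 had a median of 0.14 (camera adjusted p = 0.00665, 0.245 with an estimated correlation, and 0.221 and 0.915 in fits 2 and 3). HLA-C rose from 633 ± 35.7 to 720 ± 35.9 CPM (log2 fold change 0.19, SE 0.041, edgeR adjusted p = 0.00447). Of genes for G2/M and mitosis, 1 rose, 9 fell and 14 did not pass of 24 tested, and 1 rose and 10 fell adjusted over the list alone. G2/M genes with GSK-484 had a median of -0.086 (camera adjusted p = 0.00761, 0.238 with an estimated correlation, and 0.961 and 3.88e-08 in fits 2 and 3). Their median turned sign in fit 2 (0.010). The genes KIF11 (-0.17, SE 0.035) and CCNA2 (-0.13, SE 0.038) fell and CDC20 rose (0.16, SE 0.043). In the integrated stress response list, 9 rose, 3 fell and 10 did not pass of 22 tested, and 11 rose and 3 fell adjusted over the list alone. Stress response genes with GSK-484 had a median of 0.10 (camera adjusted p = 0.0138, 0.495 with an estimated correlation, and 0.418 and 0.745 in fits 2 and 3). The genes SESN2 (0.19, SE 0.042) and CHAC1 (0.24, SE 0.059) rose and SLC7A11 fell (-0.27, SE 0.060). For MYC targets and ribosome biogenesis, 7 rose, 1 fell and 20 did not pass of 28 tested, and 8 rose and 1 fell adjusted over the list alone. Ribosome biogenesis genes with GSK-484 had a median of 0.063 (camera adjusted p = 0.0299, 0.365 with an estimated correlation, and 0.0189 and 0.31 in fits 2 and 3). The genes PES1 (0.24, SE 0.041) and BOP1 (0.28, SE 0.062) rose and WDR43 fell (-0.19, SE 0.043). In the lysosome list, 7 rose, 1 fell and 14 did not pass of 22 tested, with the same counts adjusted over the list alone. Lysosome genes with GSK-484 had a median of 0.082 (camera adjusted p = 0.0383, 0.548 with an estimated correlation, and 0.501 and 0.134 in fits 2 and 3). CTSD rose (0.26, SE 0.040) and LAMP2 fell (-0.17, SE 0.043). In fit 2, at most 2 members of any of these 5 lists were called. HLA-C, KIF11, CCNA2, CDC20, SESN2, CHAC1, SLC7A11, BOP1, WDR43, CTSD and LAMP2 were called in neither fit 2 nor fit 3, and PES1 was not called in fit 3.

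Among the largest changes with GSK-484 outside read-throughs and near copies, IDUA rose from 1.88 ± 0.108 to 3.49 ± 0.367 CPM (log2 fold change 0.89, SE 0.13, edgeR adjusted p = 0.000695) and GUCY1A2 fell (-0.70, SE 0.18). In fit 3 they were 0.15 and -0.15 (edgeR adjusted p = 0.501 and 0.737). GSK-484 calls numbered 276 in fit 2, 26 in fit 3 and 19 with the reference of fit 3 alone. TMEM198B, a transcribed pseudogene (chromosome 12, 55829608 to 55836246) named after its values were seen, was higher in all 3 fits (log2 fold change 0.41, SE 0.083, edgeR adjusted p = 0.00295). A fit of the 6 libraries of the 2 groups alone called 9 genes, and 924 and 1526 were called without untreated replicate 1 and without GSK-484 replicate 1. Scaled by total counts, 41.2% of called genes were higher against 59.8%, and with the GC trend removed 72.1% were.

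Changes were shared between compounds: 7091 genes were called in the same direction by at least 2 compounds, and 3593 with the GC trend removed. Simulated sets with unchanged groups gave a mean of 0 without a GC trend (20 sets), 3335 with the measured GC trends (10 sets) and 0.1 after these were removed. The sets with GC trends may hold too few calls, because their spread between replicates already holds the GC trend. All 6 compounds called 382 genes higher and 188 lower (126 and 345 when scaled by total counts, and 23.4 and 10.5 in the unchanged sets with GC trends), and the 5 other than JQ-1 called 563 higher and 274 lower. With the GC trend removed these fell to 14 and 7 for all 6, and to 26 and 14 for the 5. Genes shared by the most compounds included EIF3CL, PRKCSH and ANAPC2, higher with all 6, and EIF3C, lower. PRKCSH, a glucosidase subunit gene, rose by 0.20 to 0.39 and ANAPC2, an anaphase-promoting complex gene, by 0.33 to 0.61. In fit 2, ANAPC2 was called with 6 compounds (0.13 to 0.38) and PRKCSH with 4, and in fit 3 each with 1. The EIF3C pair is uncertain.

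TP-472 and GSK-591 shared 1844 higher and 1325 lower genes, where independent lists would share 471.3 and 322.8 and the unchanged sets with GC trends shared 906.9 and 509.8. In fit 2 they shared 592 and 305 (139.8 and 47.3 if independent). MS023 and GSK-591 shared 2183 and 1641, where independent lists would share 600.0 and 457.4 and those sets shared 1297 and 894.4. In fit 2 they shared 844 and 337 (200.8 and 58.9 if independent). Across genes, the correlation of fold changes between pairs of compounds ran from 0.166 (JQ-1 and UNC0642) to 0.623 (GSK-591 and GSK-484), beside 0.46 to 0.515 in the simulated sets without and 0.581 to 0.662 in those with GC trends. Covariances exceeded those of the sets with GC trends by 0.0159 (JQ-1 and UNC0642) to 0.0613 (TP-472 and JQ-1). The 3 untreated libraries cannot be split into separate controls of at least 2 each, so part of the excess may come from the shared controls.

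Scaled by total counts, some of the list calls above ended. These were Sm and PRMT genes and target genes with TP-472, p53 targets, invasive-state genes and antigen presentation with GSK-591, and ribosome biogenesis, lysosome and stress response genes with GSK-484. Stress response and hypoxia genes with MS023, interferon-stimulated genes with JQ-1 and target genes with UNC0642 were the others. Gene calls for BRD3 with JQ-1, PRMT5 with GSK-591, CDC20 with GSK-484, and MCM2, MKI67, NGFR and EHMT2 with UNC0642 ended likewise.

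Values in fits 2 and 3 above are at the preset correlation. With an estimated correlation, the calls above that held in fit 2 were stress response and G1/S genes with TP-472, NF-kB targets with UNC0642, and NF-kB targets, histone, G1/S, G2/M, anti-apoptotic, antigen presentation and oxidative stress genes with JQ-1. Those of P-TEFb genes with JQ-1 (adjusted p = 0.0609) and of the other lists above were lost. In fit 3 the same calls held, with p53 targets with GSK-591, G2/M with GSK-484, antigen presentation and hypoxia genes with MS023, P-TEFb genes with JQ-1 and G1/S with UNC0642. Some lists were called in fit 2 or fit 3 but not against untreated cells without GC correction. With TP-472, genes for G2/M and mitosis were called higher in both (median 0.13 and 0.093, camera adjusted p = 5.96e-10 and 3.85e-10, adjusted p = 0.00699 and 0.00403 with an estimated correlation). In fit 2, 17 were higher (the same adjusted over the list alone), and 5 were higher in all 3 fits. Genes of the invasive melanoma state were called lower in both (median -0.088 and -0.11, camera adjusted p = 1.08e-07 and 3.33e-09, adjusted p = 0.0402 and 0.0156 with an estimated correlation). In fit 2, 1 was higher and 11 lower (4 and 14 adjusted over the list alone), and 5 were lower in all 3 fits. Neural crest and nerve markers were called lower as well (median -0.10 and -0.18, camera adjusted p = 0.0107 and 7.43e-05, adjusted p = 0.0609 and 0.00798 with an estimated correlation). In fit 2, 2 were lower (the same adjusted over the list alone), and 1 was lower in all 3 fits. Targets of p53 were called lower too (median -0.014 and -0.033, camera adjusted p = 0.0256 and 0.0113, adjusted p = 0.128 and 0.0696 with an estimated correlation). In fit 2, 2 were higher and 6 lower (2 and 7 adjusted over the list alone), and 1 was higher and 3 lower in all 3 fits. With GSK-591, integrated stress response genes were called lower in both (median -0.024 and -0.066, camera adjusted p = 0.0256 and 6.89e-08, adjusted p = 0.283 and 0.0148 with an estimated correlation). In fit 2, 3 were higher and 6 lower (4 and 7 adjusted over the list alone), and 2 were lower in all 3 fits. Called in fit 2 alone, MAPK output was lower with GSK-484 (camera adjusted p = 0.000174), UNC0642 (0.00116) and TP-472 (0.0256), P-TEFb response genes were lower with GSK-484 (0.0211), and G2/M was higher with GSK-591 (0.0446). All 5 of these calls were lost with an estimated correlation (smallest adjusted p = 0.121). Called in fit 3 alone and kept with an estimated correlation were cholesterol synthesis with GSK-484 (camera adjusted p = 0.000113, then 0.0109) and NF-kB targets with MS023 (0.000478, then 0.0443), both higher. The other 9 called in fit 3 alone were lost with it (smallest adjusted p = 0.0519). They were pro-apoptotic genes with GSK-591 and ER chaperones with MS023, which were higher, and ER chaperones and hypoxia genes with TP-472, G1/S and oxidative stress genes with GSK-591, G1/S with GSK-484, and stress response and Sm and PRMT genes with UNC0642, which were lower. Fit 3 compares treated groups with one another, so its differences may lie in the reference.

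Against untreated cells and without GC correction, no compound called the lists of pro-apoptotic genes (smallest camera adjusted p = 0.177, GSK-591), the melanocyte lineage (0.674, GSK-484), MAPK pathway output (0.368, UNC0642), cholesterol synthesis and uptake (0.437, GSK-484), ER chaperones and the unfolded protein response (0.318, TP-472), SWI/SNF subunits (0.192, MS023), germline genes (0.732, JQ-1), KRAB zinc fingers and retroelement silencing (0.465, GSK-591) or fibroblast markers (0.192, JQ-1). With JQ-1, 6 pro-apoptotic genes were higher and 11 lower of 20 tested, and 6 MAPK output genes were higher and 12 lower of 19 tested. Epithelial markers (4 genes tested) and blood cell markers (3 genes tested) were too few for a list test. In untreated cells the tight-junction gene CLDN4 averaged 141 CPM and TWIST2 29.7 CPM, while the blood cell marker PTPRC averaged 0.0356 CPM and the epithelial marker EPCAM 0.0364 CPM.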

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

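The direct contrast below was planned, and the tests on splits of the libraries were written down after the counts had been seen. Genes for G1/S and DNA replication differed between the compounds that bind bromodomains: their median was 0.80 higher (log2) with TP-472 than with JQ-1 (camera adjusted p = 8.98e-11, and adjusted p = 0.00206 with an estimated correlation). Against untreated cells, 13 of the 24 tested rose with TP-472 and 22 fell with JQ-1. This list was picked out because the difference itself was tested in the direct contrast, which leaves out the untreated group. No technical or biological explanation was tested for it.

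Each comparison of 3 libraries with 3 has 10 splits of its 6 libraries, so the share of splits with as many calls is never under 0.1, and in each of the 8 comparisons 1 split, the real one, gave as many. Fitted on its 6 libraries alone, the real split and the highest of the other splits called 3905 and 0 genes for TP-472, 3767 and 0 for GSK-591, 9 and 8 for GSK-484, 5409 and 0 for MS023, 10604 and 0 for JQ-1, 1538 and 4 for UNC0642, 11153 and 0 for TP-472 against JQ-1, and 1367 and 0 for GSK-591 against MS023. The counts of 0 are from the edgeR quasi-likelihood test.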

How the results depend on the processing

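The settings without the GC trend, with the other treated groups except JQ-1 as the reference, and without ribosomal RNA genes were added after seeing the data, and the others were planned. The cause of each change below was not tested, except where fewer libraries or a stricter threshold is the setting itself. DESeq2 called 4813 genes for TP-472, 4929 for GSK-591, 3159 for GSK-484, 6227 for MS023, 10993 for JQ-1, 2693 for UNC0642, 10791 for TP-472 against JQ-1 and 1598 for GSK-591 against MS023. A replicate block called 4654, 4864, 2744, 6300, 11000, 2354, 10864 and 1383 in that order, and residuals of libraries with the same number had a mean correlation of -0.00524 (-0.16 to 0.137, 63 pairs). RLE scaling, total counts, no filter, thinning to the smallest library and leaving out ribosomal RNA genes moved no count of called genes by over 1.5 times. A 1.5-fold threshold left 2, 2, 2, 8, 4062, 0, 3809 and 5 genes, where glmTreat of edgeR at an unadjusted p gave 97 for the count of 0.

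With the GC trend removed, 2181 genes were called for TP-472, 2348 for GSK-591, 276 for GSK-484, 2965 for MS023 and 650 for UNC0642. With the other treated groups except JQ-1 as the reference, the counts were 1296, 1136, 19, 2840 and 4145, and with both changes 1701, 1527, 26, 1986 and 4071. With the other 5 treated groups as the reference, UNC0642 gave 6386. The 2 groups fitted alone gave 9 for GSK-484 and 1538 for UNC0642. An estimated correlation left 8 of the 36 list calls. With the GC trend removed, 3593 genes were shared between compounds and 200 named pairs were called, and 157 with the other treated groups as the reference as well. List calls numbered 35 with RLE scaling, 24 with total counts, 41 without a filter, 35 with the block, 34 with the GC trend removed and 40 with the reference changed as well (24 of the 36 in each of these last 2).

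Leaving out each library in turn gave 2789 (without untreated replicate 1) to 4927 genes for TP-472, 3213 (without untreated replicate 1) to 4915 for GSK-591, 924 (without untreated replicate 1, and 1526 without GSK-484 replicate 1) to 3163 for GSK-484, 4914 to 6152 for MS023 and 10545 to 10799 for JQ-1. For UNC0642 it gave 1109 (without UNC0642 replicate 3, 1300 without UNC0642 replicate 2 and 1456 without untreated replicate 3) to 2431. TP-472 against JQ-1 gave 10333 to 10469. GSK-591 against MS023 gave 808 (without GSK-591 replicate 3, 838 without GSK-591 replicate 2, 858 without MS023 replicate 1 and 842 without MS023 replicate 2) to 1181. List calls ran from 33 to 37 and named pairs from 274 to 323.

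Camera directions turned for 3 lists: G2/M with UNC0642 (median 0.021, GC trend removed), antigen presentation with GSK-591 (median 0.030 but a downward camera direction) and lysosome with GSK-484 (-0.024), the last 2 with the GC trend removed and other treated groups as the reference. The median alone turned for G2/M with GSK-484 (0.010, GC trend removed). CALR with JQ-1 turned to -0.025 with total counts and -0.026 with the GC trend removed against the other 5. With the GC trend removed alone, log2 values turned to 0.039 for LAMP2 and 0.040 for MDM2 with GSK-591, -0.012 for HLA-E and -0.013 for CARM1 with MS023, and -0.013 for NGFR with UNC0642. With the reference changed as well, they turned with TP-472 for COL6A2 (-0.071), PRMT3 (0.051), BRD9 (-0.038), EHMT2 (-0.015) and CTSD (-0.047), and with GSK-591 for LAMP2 (0.070), MDM2 (0.15), TP53INP1 (0.052), NT5E (0.16) and PMAIP1 (0.0066), MDM2 and NT5E then being called the other way (edgeR adjusted p = 0.00114 and 7.74e-05). In the same setting they turned with GSK-484 for HLA-C (-0.048), CDC20 (-0.069), CHAC1 (-0.036), SLC7A11 (0.018), BOP1 (-0.019) and CTSD (-0.0096), with MS023 for LAMP2 (0.020), XIAP (0.0044) and SLC7A11 (0.027), and with UNC0642 for ITGB1 (0.0057), MCM2 (-0.011), NGFR (-0.0050) and XIAP (0.0052).

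List calls ended without untreated replicate 1 (matrix and Sm genes with TP-472, lysosome with GSK-484), 2 (matrix genes with TP-472, p53 targets with GSK-591, neural crest with UNC0642) or 3 (targets with TP-472 and UNC0642, invasive state with GSK-591, G2/M with UNC0642). They also ended without TP-472 replicate 2 (targets) or 3 (matrix and Sm genes), GSK-484 replicate 1 (ribosome biogenesis, stress response) or 2 (lysosome), and UNC0642 replicate 1 (G2/M, neural crest) or 2 (targets). The matrix call with TP-472 ended with the block and its target call with RLE scaling. Gene calls ended without at least 1 library for BCL2L2 and PRMT3 with TP-472, LAMP2, MDM2 and TP53INP1 with GSK-591, and CCNA2, CDC20, SLC7A11, LAMP2 and GUCY1A2 with GSK-484. The same held for PRMT6 with MS023 and for ITGB1, CSF2, MCM2, MKI67, NGFR, XIAP, EHMT1 and EHMT2 with UNC0642.

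Among named genes, the GC settings left 278 values on the same side of the threshold and 94 below it, leaving out a library 1208 and 46, and the other settings 1035 and 9. Lists gave 48 and 21, 197 and 19, and, apart from the correlation, 166 and 14 in that order. At this depth and with 3 replicates, 36.8 to 48.7% of simulated 1.2-fold changes were recovered. With only 200 genes changed there, this need not hold for the data.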

Other observations

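The genes in the next paragraph were chosen after their values were seen, and of the tests reported after them only that of depth for zinc finger genes was planned before its result was seen.

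JQ-1 changed further genes far beyond the spread between replicates. NEAT1, a nuclear long noncoding RNA (chromosome 11, 65422774 to 65445540), rose from 162 ± 6.38 to 1554 ± 54.9 CPM (log2 fold change 3.26, SE 0.040, edgeR adjusted p = 3.71e-25), and TXNIP, an inhibitor of thioredoxin, and PEG10 rose by 3.04 and 3.59. PPARG, a nuclear receptor gene, fell (-4.97), as did the cytokine genes IL6 (-4.19) and CCL2 (-4.45). With MS023, NT5E, an ectonucleotidase, fell from 238 ± 1.43 to 104 ± 1.22 CPM (log2 fold change -1.20, SE 0.031, edgeR adjusted p = 1.26e-17), with PRKACB (-1.15, SE 0.060) and FBLN7 (-0.81, SE 0.12). With TP-472, IGFN1 (-0.83, SE 0.10), EHF (-0.64, SE 0.070) and CCR1 (-0.69, SE 0.064) fell and GEMIN8 (0.50, SE 0.084) and KRT15 (0.49, SE 0.051) rose. With UNC0642, the hemidesmosome collagen COL17A1 and the secretogranin gene SCG2 rose (0.60, SE 0.077 and 0.51, SE 0.074), and with GSK-591, OLFML2B rose (0.59, SE 0.12) and ENTPD5 (-0.81, SE 0.15) and PHF7 (-0.74, SE 0.13) fell.

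Fold changes against untreated cells followed transcript GC content with each of the 6 compounds, with slopes of 0.11 to 0.22 in log2 per 10 percentage points. Untreated slopes lay below all treated ones (two-sided exact permutation p = 0.000752, libraries taken as independent). A GC trend in the 3 untreated libraries is thus a candidate explanation. A different share of ribosomal RNA is argued against as the whole cause. Of the 18 treated libraries, 16 had a share within the range of the untreated ones (4.99 to 9.47%), yet the lowest slope among them was -0.0363, above the highest untreated slope of -0.0961. A response to handling or to a vehicle that all treated cultures share cannot be told apart from it, because each treated group would show it, the lowest slope being 0.112, and no vehicle control is named. That a BET, PRMT or EHMT inhibitor and the others would each act alike on GC-rich genes was not tested.

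If the GC trend and the untreated libraries were the whole cause of a compound's calls, almost none would be found in all 3 fits. The reference of fit 3 holds no untreated library, and in 10 simulated sets with the measured GC trends and no changed gene edgeR called at most 1 gene for any compound in it. In the data fit 3 called 1701 genes for TP-472, 1527 for GSK-591, 1986 for MS023, 4071 for UNC0642 and 26 for GSK-484. In that order, 11.9, 12.8, 14.2, 12.7 and 0.0351% (1 gene) of calls were found in all 3 fits. This argues against the GC trend as fitted here, with the untreated libraries, as the whole cause except for GSK-484, where that stays open. Against untreated cells the simulated sets gave at most 2198, 2549, 4886, 96 and 1115 calls, and the data 4788, 4952, 6411, 2448 and 2872. The GC trend alone thus gave few UNC0642 calls, but most calls may still rest on it and the untreated libraries. Differences in handling between treated groups stay open.

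Genes of the ZNF family on chromosome 19, which encode zinc finger proteins, were lower as a set with UNC0642, though most members did not pass. With the GC trend removed, 16 of the 231 were lower against untreated cells (19 adjusted over the set alone), with a median of -0.083 (camera p = 3.92e-09, and p = 0.00288 with an estimated correlation), which argues against the GC trend as the cause. Against the other treated groups, 67 were lower and 10 higher (68 and 10 adjusted over the set alone), with a median of -0.10 (camera p = 1.1e-05, and p = 0.0157 with an estimated correlation). There the 144 genes with whole counts (camera p = 0.000277, and p = 0.0137 with an estimated correlation) argue against shared reads. The 229 left after thinning to the smallest library (camera p = 0.000149, and p = 0.021 with an estimated correlation) argue against depth. The 737 other protein-coding genes of chromosome 19 had a median of 0.017 against untreated cells, which did not pass camera's threshold of 0.05. Against the other treated groups they were lower too (median -0.046) and did pass it, so that contrast is not specific to ZNF genes. The 230 ZNF genes on other chromosomes had medians of 0.034 and 0.038 and passed it in neither contrast. ZNF genes with GSK-484 were higher than in the other treated groups (median 0.058, past the same threshold), a reference that includes UNC0642. A lower level of these genes with EHMT1 and EHMT2 inhibited may be a response to the compound, a hypothesis found and tested on the same data, and handling or culture differences between groups stay open.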
